A study of Homo sapiens with 16 samples.

How the data were processed

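Total RNA of 16 HEK293T samples was sequenced, 4 samples in each of 4 groups, and samples were assigned to groups by their titles and treatment labels. The labels of the DMSO samples list no compound while their titles name DMSO, and the treatment text gives pinometostat in millimolar where the sample field gives 2.5 µM; the sample field was used. Per the labels' protocols, cells grew in DMEM with serum, and libraries were made and sequenced by a service provider. The aligner, the read counter, their versions, the strand setting and the library selection are not given in the sources used here.

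The authors deposited whole-number counts per gene for each library and a table of the same counts for the series, identical in all 920000 cells, so that the series table was not analysed separately. The deposited TPM values, 4 decimals each, equal the counts divided by the gene's exonic length in the files and scaled to a fixed sum. Each library had 57500 genes, of which 57015 had a symbol in the files. Coordinates are those in the files: of 56898 gene identifiers shared with GENCODE release 29 (GRCh38), 54773 (96.3%) had the same start and end. Every column of the series tables matched a sample, and 740 of 740 members of the 24 gene lists matched a gene. Depth ran from 17779692 to 27599686 counts per library. A pair of samples of 1 group never matched within sampling noise: the smallest chi-square per degree of freedom over genes of any replicate pair was 3.77.

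Genes were kept with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 17306. Counts were scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3 over all 16 libraries, with a mean per group, 12 residual degrees of freedom, a common dispersion of 0.0307 and 5.83 prior degrees of freedom. Each contrast was taken against the same 4 H2A libraries with DMSO, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a fold change is its size divided by the square root of the F statistic. All groups share the estimate of each gene's spread, so a library that stands apart in another group enters every contrast. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, for lists with at least 5 tested members, and again with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, in a single direction. The calls of each list's members come from the gene test and, as "adjusted over the list alone", from Benjamini-Hochberg adjustment within the list.

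The groups, tests, gene lists, other settings and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 largest rises and the 12 largest falls among genes with an adjusted p below 0.05, a mean of at least 5 CPM over the 16 libraries, a symbol and groups that do not overlap. It added HEXIM1, SERPINI1, MYC, BRD2, BRD3, DOT1L, HOXA9, MEIS1 and the H2A genes with at least 5 CPM, and up to 4 members per list with the smallest adjusted p. Other list members are given as examples of a count. Some of the genes that the rule takes are not reported here. The lists held BET-inhibitor-induced markers, BET proteins with P-TEFb and elongation factors, MYC targets, immediate-early genes, replication-dependent and variant histones, DOT1L partners, HOX and MEIS/PBX genes, cholesterol synthesis, the ATF4 response, ER chaperones, heat shock, p53 targets, interferon-stimulated genes, S phase, G2/M, hypoxia and glycolysis, mitochondrial mRNAs, ribosomal proteins, chromatin remodellers, and kidney, neuronal, mesenchymal and blood cell markers.

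The other settings chosen then were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library size alone, upper quartile scaling, no filter, a filter of 50 counts in 4 libraries, the 8 libraries of both groups alone, a block for the replicate number, a threshold of 0.01, limma on log2(TPM + 1), and each library of a comparison left out in turn. Chosen after seeing the data were the fits without JQ1 replicate 1 and E92K replicate 4, without each library outside the comparison, with library quality weights (all 16 or 8 libraries), with the mitochondrial share as a covariate and with a loess offset for transcript GC content. Comparisons that share controls were set beside 100 simulations of unchanged groups, n1 × n2 / N, and the controls split in all 6 assignments of 2 and 2. The difference of effects was tested over all genes and lists in the same fit. It is reported here for named genes only, without counts or list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

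The gene test was tested on simulated data with 200 changed genes. For E92K (17028 genes) it recovered 26.9%, 64.2% and 97.0% of genes changed by 1.5, 2 and 4 fold, with 1 false call. For JQ1 (17007 genes) it recovered 19.4%, 70.1% and 90.9%, with 5 false calls, and for pinometostat (17002 genes) 26.9%, 62.7% and 90.9%, with 8. The list test called 1 of 1 shifted lists and 0 others of 24 in 17021 simulated genes of the JQ1 comparison. The simulated genes varied independently of each other, so this could not show false calls in lists whose genes vary together.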

Results

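RNA was sequenced from HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen. The cells held a lentiviral vector for histone H2A or for H2A(E92K), in which a glutamate of the nucleosome acidic patch, the docking surface of many chromatin proteins, is replaced by lysine. The 16 libraries fell into 4 groups of 4: H2A cells given DMSO, E92K cells given DMSO, H2A cells given 1 µM JQ1 for 3 h, and H2A cells given 2.5 µM pinometostat for 24 h. No time with DMSO was found in the labels, and the same H2A libraries with DMSO serve the 3 h and the 24 h comparison. A difference in time or handling therefore cannot be told apart from the compound. JQ1 displaces BET proteins from acetylated chromatin, and pinometostat inhibits DOT1L, the methyltransferase of lysine in the core of histone H3. Total counts per library ran from 17779692 to 27599686. The group means were 25638212 ± 1614387 (SD, n = 4) for H2A with DMSO, 23773565.5 ± 1444450.0 for E92K, 20188969.5 ± 1776471 for JQ1 and 21734079 ± 990480.0 for pinometostat. The labels number the samples without stating separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are log2 fold changes ± SE against the 4 H2A libraries with DMSO, with n = 4 per group, and levels in CPM, with library sizes scaled by TMM, are means ± SD.

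A pair of libraries stood apart. The mitochondrial genome took 16.5% of the counts of JQ1 replicate 1 against 3.04% to 3.69% in the other JQ1 libraries, and 7.45% in E92K replicate 4, where the group mean was 5.09 ± 1.65%. The shares were 3.87 ± 0.160% in H2A with DMSO and 4.61 ± 0.288% with pinometostat.

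**Figure D1:**
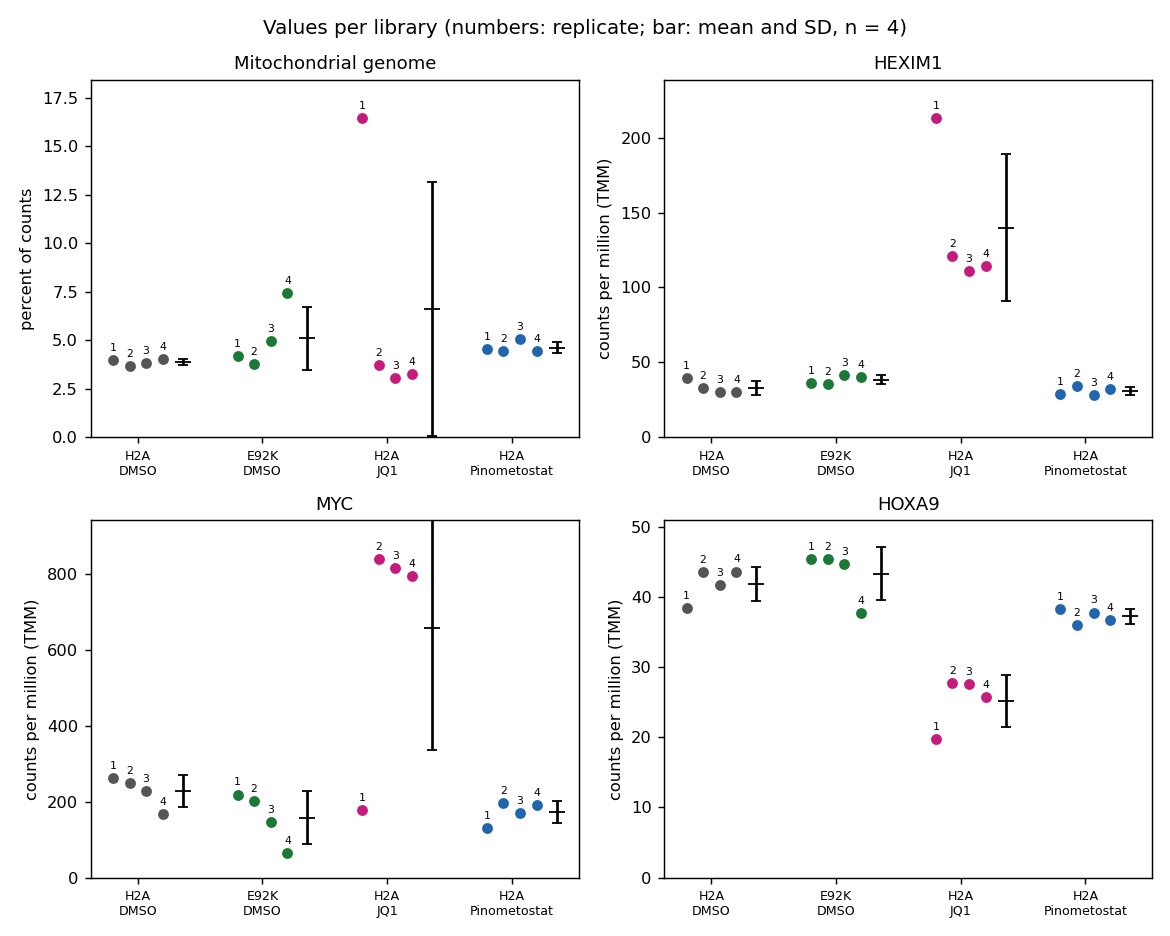
Mitochondrial share of counts (percent) and CPM of HEXIM1, MYC and HOXA9 in each of the 16 libraries by group, with points for libraries and bars for the mean and SD (n = 4). JQ1 replicate 1 lies at 16.5% mitochondrial counts and 178.4 CPM of MYC, where the other JQ1 libraries lie at 796.6 to 841.2 CPM.

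The comparison of JQ1 with DMSO asked which transcripts differed after 3 h of BET bromodomain inhibition. HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101, GRCh38), an inhibitor of the elongation kinase P-TEFb and a common marker of BET inhibition, rose by 2.08 ± 0.18, from 33.0 ± 4.60 to 140.0 ± 49.0 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.30e-07). Of 33 replication-dependent histone genes 26 rose, led by HIST1H2AC (ENSG00000180573, chromosome 6, 26124145 to 26139116), which went from 4.28 ± 0.435 to 29.01 ± 6.07 CPM, a log2 fold change of 2.76 ± 0.18 (edgeR Benjamini-Hochberg adjusted p = 4.57e-08). Of 41 HOX, MEIS and PBX genes, 27 fell and 0 rose. OTX2 (ENSG00000165588, chromosome 14, 56799905 to 56810479), a homeodomain factor of the forebrain, fell by 3.19 on the log2 scale (SE 0.27, edgeR Benjamini-Hochberg adjusted p = 3.23e-07). The proto-oncogene MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) rose by 1.53 ± 0.38, from 227.5 ± 42.3 to 658.0 ± 320.3 CPM (edgeR Benjamini-Hochberg adjusted p = 0.00948), although JQ1 replicate 1 lay at 178.4 CPM.

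Of 17306 genes tested, 3044 changed with JQ1 at an adjusted p below 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg). Of these, 1239 were higher and 1805 lower, with 273 higher and 649 lower by at least 1 on the log2 scale. The genes named next are the largest only among those with a mean of at least 5 CPM, a symbol and groups that do not overlap. Behind HIST1H2AC, the largest rises were SERTAD1 (2.58 ± 0.17), a transcription regulator that binds CDK4, HIST1H2BD (2.38 ± 0.17), the stress-inducible GADD45B (2.29 ± 0.20), the immediate-early gene ARC (2.14 ± 0.28), HEXIM1, SMG1P7 (2.04 ± 0.42) and FAM222A (2.02 ± 0.18). The heat shock gene HSPA1B (1.82 ± 0.32) and the AP-1 genes JUND (2.03 ± 0.28), FOS (1.82 ± 0.23) and JUN (1.77 ± 0.14) followed. SMG1P7 and HSPA1B have near-identical copies, so their values are uncertain. The largest falls were ZFP37 (-3.22 ± 0.20), OTX2, the LIM-homeodomain gene LHX8 (-3.13 ± 0.22), INHBE (-2.83 ± 0.45), the potassium channel subunit KCNJ8 (-2.64 ± 0.19) and the macrophage growth factor CSF1 (-2.59 ± 0.19). The homeodomain gene NKX2-4 (-2.28 ± 0.19), DACT1 (-2.25 ± 0.17), PRDM13 (-2.21 ± 0.23), the chondroitin sulfotransferase CHST3 (-2.17 ± 0.17), PPP1R3B (-2.10 ± 0.21) and SLITRK3 (-2.08 ± 0.16) fell next. All 24 of these genes named by size kept their call in each of the 33 other settings.

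Among the genes of the BET proteins, BRD2 rose by 1.06 ± 0.11 (edgeR Benjamini-Hochberg adjusted p = 2.90e-06), while BRD3 (0.29 ± 0.12, adjusted p = 0.112) did not pass. BRD3 was called higher in 5 of the 33 other settings. DOT1L did not differ past the threshold (0.03 ± 0.15, edgeR Benjamini-Hochberg adjusted p = 0.914). HOXA9 (ENSG00000078399, chromosome 7, 27162435 to 27175180) fell by 0.73 (SE 0.11, edgeR Benjamini-Hochberg adjusted p = 1.25e-04). Its cofactor MEIS1 (ENSG00000143995, chromosome 2, 66433452 to 66573869) fell by 0.80 (SE 0.11, edgeR Benjamini-Hochberg adjusted p = 5.79e-05) on the log2 scale. SERPINI1, another marker of BET inhibition, rose by 0.70 ± 0.16 (edgeR Benjamini-Hochberg adjusted p = 0.00627). Of the H2A genes with at least 5 CPM, H2AFX (1.14 ± 0.14), HIST3H2A (0.87 ± 0.16), H2AFV (0.33 ± 0.09) and HIST1H2AC rose, where H2AFV lost its call in 7 of the 33 other settings, and H2AFJ, H2AFY, H2AFY2 and H2AFZ did not pass.

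Of 24 gene lists, 10 differed from other genes with JQ1 (limma camera, Benjamini-Hochberg over lists), and 4 of them held with an estimated inter-gene correlation. Of the 8 BET-inhibitor-induced markers, 7 rose and 0 fell (8 rose adjusted over the list alone), among them HIST1H2BK (0.92 ± 0.10) and HIST1H2BJ (1.64 ± 0.20). HIST1H2BK, HIST1H2BJ, HIST1H2BD and HIST2H2BE of this list are also replication-dependent histone genes, so the calls of these lists are not independent. For the BET marker list, camera gave a Benjamini-Hochberg adjusted p = 1.27e-09 (adjusted p = 0.000572 with an estimated correlation). Messages of replication-dependent histone genes end in a stem-loop in place of a poly(A) tail, and 33 of the 66 genes of that list passed the filter. Of these 33, 26 rose and 0 fell (29 rose adjusted over the list alone), with a median of 1.35. For the replication-dependent histone list, camera gave a Benjamini-Hochberg adjusted p = 2.18e-19 (adjusted p = 0.00107 with an estimated correlation). These genes are short and similar in sequence, so the share of each is uncertain. Of 41 HOX, MEIS and PBX genes, which set body axis identity, 27 fell and 0 rose (29 fell adjusted over the list alone), with a median of -0.73. HOXB2 (-1.55 ± 0.17), HOXC11 (-1.35 ± 0.13) and HOXB8 (-1.17 ± 0.13) were among them, and the list's camera Benjamini-Hochberg adjusted p was 2.18e-19 (adjusted p = 0.00145 with an estimated correlation). Of 13 kidney developmental markers, 8 fell and 1 rose (9 and 1 adjusted over the list alone). For the kidney list, camera gave a Benjamini-Hochberg adjusted p = 0.000231 (adjusted p = 0.0290 with an estimated correlation). WT1 (-1.96 ± 0.23), SIX2 (-0.85 ± 0.13), EYA1 (-0.89 ± 0.14) and GATA3 (-1.35 ± 0.17) were among those that fell, and CITED1 (0.66) rose.

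The other 6 called lists lost the call with an estimated correlation. Of 34 genes for BET proteins, P-TEFb and elongation factors, 7 rose, including CDK9 (0.71 ± 0.09) and CTR9 (0.55 ± 0.12), and HEXIM2 (-0.81) fell, with the same counts adjusted over the list alone. The list's camera Benjamini-Hochberg adjusted p was 0.0216 (adjusted p = 0.214 with an estimated correlation). Its median turned negative with library size alone (-0.01) and on TPM (-0.17), and its call was lost without JQ1 replicate 4 (camera Benjamini-Hochberg adjusted p = 0.0528). Of 33 immediate-early genes, 12 rose, such as EGR1 (1.71 ± 0.22) and IER5 (1.09 ± 0.13), and 4 fell, namely FOSL1 (-1.83), MAFF (-1.04), NR4A1 (-0.93) and NR4A3 (-0.86). Adjusted over the list alone, 15 rose and 7 fell, and the list had a camera Benjamini-Hochberg adjusted p = 0.00698 (adjusted p = 0.214 with an estimated correlation). Of 11 variant and replication-independent histone genes, 6 rose, including H3F3B (0.66 ± 0.09) and H1F0 (0.42 ± 0.11), and 0 fell (8 rose adjusted over the list alone). For the variant histone list, camera gave a Benjamini-Hochberg adjusted p = 0.00111 (adjusted p = 0.168 with an estimated correlation). Their mean was 8.069 log2 CPM in JQ1 replicate 1 against 7.746 to 7.798 in the other JQ1 libraries. Of 24 cholesterol synthesis and uptake genes, 7 rose, including the squalene epoxidase SQLE (0.86 ± 0.11) and HMGCS1 (0.82 ± 0.17), and 0 fell (11 rose adjusted over the list alone). For the cholesterol list, camera gave a Benjamini-Hochberg adjusted p = 0.00114 (adjusted p = 0.397 with an estimated correlation), and the median turned to -0.02 on TPM. The list mean of JQ1 replicate 1, 6.493 log2 CPM, lay below all 4 DMSO libraries (6.541 to 6.633) and those of the other JQ1 libraries above them (6.873 to 7.046). Of 18 heat shock genes, 4 rose, HSPA1A (1.87 ± 0.30), HSPA1B, DNAJB1 (0.88 ± 0.22) and STIP1 (0.42 ± 0.10), and 0 fell, with the same counts adjusted over the list alone. The camera Benjamini-Hochberg adjusted p was 0.00656 (adjusted p = 0.266 with an estimated correlation), and the median turned to -0.08 on TPM. The 77 cytosolic ribosomal protein genes had a median of 0.22 (-0.09 on TPM), with 0 genes passing alone or adjusted over the list alone, and a camera Benjamini-Hochberg adjusted p = 0.000231 (adjusted p = 0.690 with an estimated correlation). Their mean was 11.064 log2 CPM in JQ1 replicate 1, 10.735 in replicates 2 and 3 and 10.584 in replicate 4, against 10.348 to 10.731 with DMSO.

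**Figure D2:**
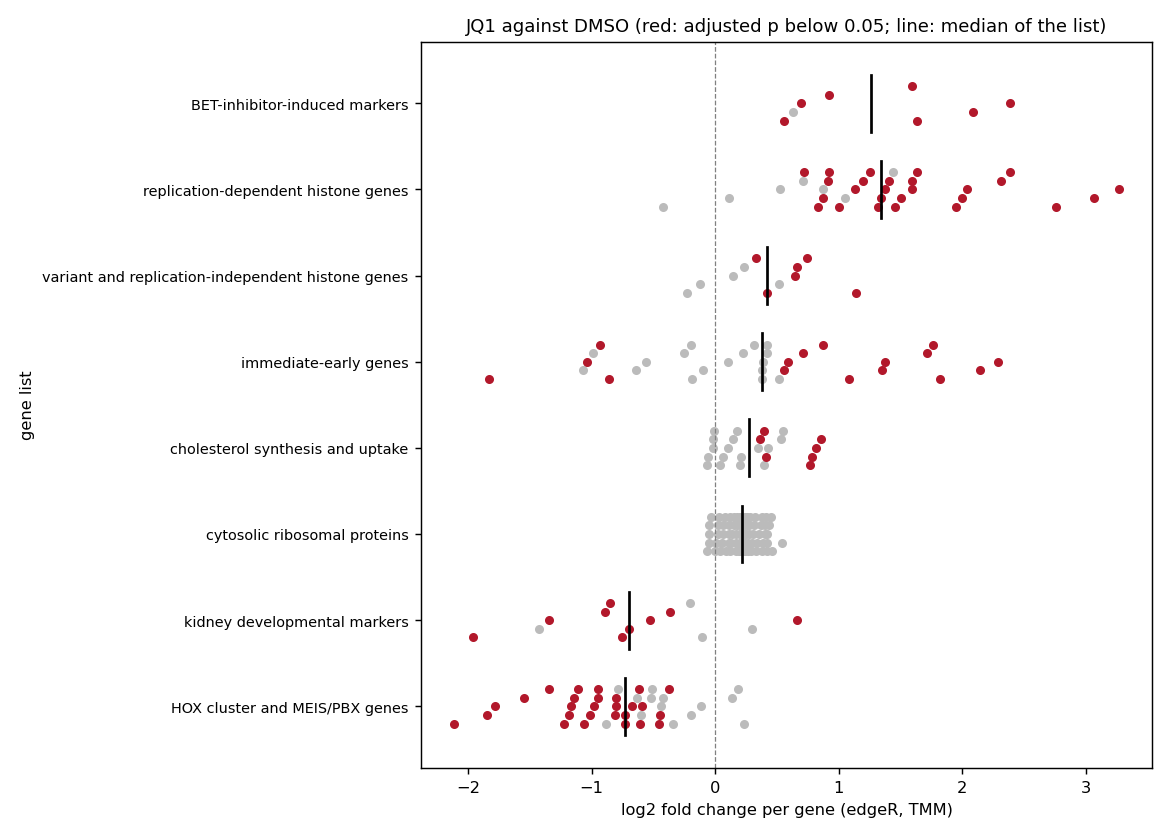
Log2 fold change of JQ1 against DMSO (n = 4 per group, TMM scaling) for the tested members of each gene list, with points for genes, red for an adjusted p below 0.05 and a line for the median. The median was 1.35 for replication-dependent histone genes and -0.73 for HOX, MEIS and PBX genes, and both kept their sign under every scaling tried, while 11 other lists changed the sign of theirs under library size, TPM or upper quartile scaling. The median of all genes moved as well, from 0.04 with TMM to -0.14 with library size and -0.21 on TPM. A change of sign alone therefore does not remove a list's difference from other genes.

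The remaining 14 lists were not called with JQ1, and in most of them members went both ways. Among these, the blood cell markers had too few tested members for a list test. Of 61 MYC target and ribosome biogenesis genes, 6 rose, such as NOP56 (0.41 ± 0.11), and 3 fell, DUSP2 (-2.14 ± 0.23), PLK4 (-0.65 ± 0.10) and SLC19A1 (-0.33), with 3 and 2 adjusted over the list alone. Of 28 ATF4 amino acid response genes, 5 fell, including TRIB3 (-1.57 ± 0.17), ADM2 (-1.80 ± 0.32) and VLDLR (-1.18 ± 0.16), and ATF4 (0.35) and ATF5 (0.46) rose. Of 17 ER chaperone genes, SYVN1 (0.47 ± 0.10) and CRELD2 (0.40 ± 0.12) rose and XBP1 (-0.68 ± 0.17), a transcription factor of the unfolded protein response, fell, with 3 and 1 adjusted over the list alone. Of 24 p53 targets, 5 fell, including PHLDA3 (-1.31 ± 0.21), FAS (-1.20 ± 0.21) and MDM2 (-0.58 ± 0.09), and PLK2 (0.47) and FDXR (0.31) rose, with 5 and 3 adjusted over the list alone. Of 23 interferon-stimulated genes, IFIT5 (-1.62 ± 0.13), IFIT1 (-1.22 ± 0.17), IRF1 and USP18 (-0.43) fell, and IRF7 (1.75 ± 0.39) and IFI27 (0.85) rose. Of 43 S phase genes, 7 rose, such as LIG1 (0.58 ± 0.12) and CDC6 (0.42 ± 0.09), and 5 fell, such as E2F2 (-1.61 ± 0.15), with 8 and 5 adjusted over the list alone. Of 41 G2/M genes, ANLN (0.53 ± 0.15) rose and AURKA (-0.65 ± 0.15) and KIF14 (-0.41 ± 0.12) fell. Of 32 hypoxia and glycolysis genes, 6 fell, including the glucose transporter SLC2A3 (-1.23 ± 0.24), and the demethylase KDM3A (0.53 ± 0.12) rose. Of 41 chromatin remodeller genes, 5 rose, such as CHD2 (0.75 ± 0.21), and YEATS4 (-0.57 ± 0.15) fell, with 4 and 1 adjusted over the list alone. Of 14 neuronal markers, NEFM (1.01 ± 0.28) and TUBB3 (0.85 ± 0.29) rose and NEUROG2 (-1.26 ± 0.21) and SOX2 (-0.47 ± 0.15) fell. Of 18 mesenchymal markers, the transcription factor SNAI2 rose (82.4 ± 9.57 against 33.5 ± 1.57 CPM). Of 11 genes for DOT1L and its partners and 3 blood cell markers, 0 passed. The counts adjusted over the list alone were the same for the lists without a second count. The 13 mitochondrially encoded mRNAs had a median of 1.08 with 0 passing over all genes and 13 rising adjusted over the list alone, and their mean was 13.42 log2 CPM in JQ1 replicate 1 against 10.69 to 10.98 in the other JQ1 libraries.

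Some lists changed their call in other settings. Without JQ1 replicate 1, the ER chaperones were called (camera Benjamini-Hochberg adjusted p = 0.0199). Without H2A with DMSO replicate 4 the MYC targets were called (adjusted p = 0.0444), without H2A with DMSO replicate 1 the chromatin remodellers (0.0198, and 0.0417 with the GC trend removed), and without JQ1 replicate 3 the hypoxia genes (0.0447). The mesenchymal markers were called without H2A with DMSO replicate 1 or 3 or JQ1 replicate 2, 3 or 4 (camera adjusted p from 0.0185 to 0.0496), with the replicate block (0.0256) and with fry (adjusted p = 0.0301). The mitochondrial mRNAs were called without JQ1 replicate 2, 3 or 4, E92K replicate 4 or H2A with DMSO replicate 4 (camera adjusted p from 0.00759 to 0.0476), with the replicate block (0.0422) and with library size alone (0.00224). With fry the interferon-stimulated genes were called (adjusted p = 0.00592) and the ribosomal protein genes were not (0.224). The count of 3044 genes was 1872 with the 8 libraries of both groups alone and 5762 with library quality weights. In 20.5% of tested genes the groups did not overlap, where chance gives 2.86%. The share of changed genes that were higher, 40.7%, depended on the setting. It was 14.25% with library size alone, 27.4% with the upper quartile, 8.77% on TPM, 48.0% with the GC trend removed and 50.7% with library quality weights. The median of all genes moved from 0.04 with TMM to -0.14 with library size and -0.21 on TPM. On TPM, MYC and SERPINI1 lost their call, and MYC did so with the replicate block on the 8 libraries.

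The comparison of pinometostat with DMSO asked which transcripts differed after 24 h of DOT1L inhibition. Of 77 cytosolic ribosomal protein genes 23 rose, and the call of that list was lost with an estimated correlation (camera Benjamini-Hochberg adjusted p = 0.297). RPL26 (ENSG00000161970, chromosome 17, 8377520 to 8383213) rose by 0.83 ± 0.13, from 918 ± 146 to 1634.7 ± 86.1 CPM (edgeR Benjamini-Hochberg adjusted p = 0.00428). RPS15A (0.84 ± 0.14), RPS12 (0.82 ± 0.13) and RPS13 (0.79 ± 0.12) rose as well. The alanyl-tRNA synthetase AARS (-0.72 ± 0.12) and the serine synthesis enzyme PHGDH (-0.58 ± 0.10) fell. The ER chaperone HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) fell by 0.62 (SE 0.15, edgeR Benjamini-Hochberg adjusted p = 0.0201). Transcripts of DOT1L itself (ENSG00000104885, chromosome 19, 2164149 to 2232578) did not differ past the threshold (-0.27 ± 0.15, edgeR Benjamini-Hochberg adjusted p = 0.274). Neither did HOXA9 (-0.17 ± 0.11, adjusted p = 0.344) or MEIS1 (-0.07 ± 0.11, adjusted p = 0.737), which depend on DOT1L in leukaemias with KMT2A fusions. Changes were smaller in size than with JQ1, with a median absolute log2 fold change of 0.51 among the changed genes against 0.72.

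In all, 1419 of 17306 genes changed with pinometostat (edgeR quasi-likelihood, Benjamini-Hochberg): 626 were higher and 793 lower, with 96 higher and 10 lower by at least 1 on the log2 scale. The ranking by size below is again limited to genes with at least 5 CPM, a symbol and groups that do not overlap. The largest rises were mostly of non-coding genes and pseudogenes: XIST (2.29 ± 0.43), the RNA that coats the inactive X chromosome, AL035425.4 (1.51 ± 0.46), GOLGA8A (1.37 ± 0.39), HERC2P2 (1.32 ± 0.31), SEC31B (1.29 ± 0.36) and RSRP1 (1.27 ± 0.22). The others were AC083843.3 (1.23 ± 0.34), AHSA2P (1.11 ± 0.29), AL133325.3 (1.08 ± 0.28), AL390728.4 (1.08 ± 0.26), PRSS30P (1.07 ± 0.24) and PABPC1L (1.05 ± 0.26). GOLGA8A and HERC2P2 belong to families of near-identical copies and are uncertain, and the strand used in counting is not given, so reads of overlapping and antisense genes cannot be separated. The largest falls were HSPA2 (-0.98 ± 0.25), a chaperone, LMTK3 (-0.93 ± 0.21), ZSWIM4 (-0.87 ± 0.17), the tubulin gene TUBB4A (-0.84 ± 0.17), EFHD1 (-0.83 ± 0.12) and the elongation factor EEF1A2 (-0.83 ± 0.13). They were followed by MAP1S (-0.81 ± 0.17), WIPF3 (-0.79 ± 0.14), CILP2 (-0.79 ± 0.15), the junction protein gene JUP (-0.79 ± 0.13), the collagen gene COL2A1 (-0.78 ± 0.12) and ATF5 (-0.77 ± 0.15), a transcription factor of the amino acid response. EEF1A2 (ENSG00000101210, chromosome 20, 63488013 to 63499315) went from 336.0 ± 38.1 to 189.3 ± 14.9 CPM (edgeR Benjamini-Hochberg adjusted p = 0.00428). Of these 24 genes named by size, 9 kept their call in all of the 33 other settings and 15 lost it in at least 1, AL035425.4 in 20 and GOLGA8A in 12 of them.

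By annotated type, 114 of 2338 long non-coding genes were higher and 2 lower, and 65 of 860 pseudogenes were higher and 3 lower, against 444 higher and 788 lower of 13972 protein-coding genes. Non-coding nuclear genes took 1.94 ± 0.0983% of the counts with pinometostat and 1.52 ± 0.0765% with DMSO. Of the fixed genes, HEXIM1 (-0.10, adjusted p = 0.751), MYC (-0.40, adjusted p = 0.538), BRD2 (-0.25, adjusted p = 0.142) and BRD3 (-0.37, adjusted p = 0.0645) did not pass the edgeR test with Benjamini-Hochberg adjustment. In the 33 other settings BRD3 was called lower in 14, BRD2 in 7, MYC in 3 and HEXIM1 in 0. H2AFY2, which encodes a macroH2A, fell by 0.31 (SE 0.08, edgeR Benjamini-Hochberg adjusted p = 0.0325), a call lost in 11 of the 33 other settings.

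Of the 24 lists, 11 were called with pinometostat (limma camera, Benjamini-Hochberg over lists), and 0 of them held with an estimated correlation, where the adjusted p = 0.297 for each of these lists except hypoxia (adjusted p = 0.699 with an estimated correlation). Of 77 cytosolic ribosomal protein genes, 23 rose and 0 fell (44 rose adjusted over the list alone), with a median of 0.40. For the ribosomal protein list, camera gave a Benjamini-Hochberg adjusted p = 3.78e-18 (adjusted p = 0.297 with an estimated correlation). They took 19.5 ± 0.520% of all counts with pinometostat and 15.5 ± 1.32% with DMSO, and with the 8 libraries of both groups alone 61 of them rose. Of 28 ATF4 amino acid response genes, 6 fell, AARS, PHGDH, ATF5, PCK2 (-0.61 ± 0.13), SLC7A5 (-0.61) and GARS (-0.52), and 0 rose (8 fell adjusted over the list alone). For the ATF4 list, camera gave a Benjamini-Hochberg adjusted p = 4.50e-06 (adjusted p = 0.297 with an estimated correlation). The list mean of pinometostat replicate 1, 7.117 log2 CPM, lay above all 4 DMSO libraries (6.796 to 7.054), and those of the other pinometostat libraries lay below them (6.387 to 6.602). Of 17 ER chaperone and unfolded protein response genes, 4 fell, HSPA5, PDIA4 (-0.43 ± 0.11), SYVN1 (-0.41 ± 0.10) and CALR (-0.39 ± 0.12), and 0 rose (8 fell adjusted over the list alone). For the ER chaperone list, camera gave a Benjamini-Hochberg adjusted p = 0.00114 (adjusted p = 0.297 with an estimated correlation). Of 18 heat shock genes, BAG3 (-0.61 ± 0.11), DNAJA1 (-0.40 ± 0.11) and STIP1 (-0.33 ± 0.10) fell (4 fell adjusted over the list alone). For the heat shock list, camera gave a Benjamini-Hochberg adjusted p = 0.0137 (0.0658 without H2A with DMSO replicate 4, and adjusted p = 0.297 with an estimated correlation). The list mean of pinometostat replicate 1, 7.006 log2 CPM, lay below all 4 DMSO libraries (7.334 to 7.577), and those of the other pinometostat libraries lay within their range (7.394 to 7.400). Of 34 genes for BET proteins, P-TEFb and elongation factors, 6 fell, including NELFA (-0.71 ± 0.14) and NELFB (-0.46 ± 0.11) of the pausing factor NELF, and CCNT2 (0.46 ± 0.11) rose (9 and 2 adjusted over the list alone). For the elongation factor list, camera gave a Benjamini-Hochberg adjusted p = 0.0137 (adjusted p = 0.297 with an estimated correlation).

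In the other called lists few members passed. Of 41 HOX, MEIS and PBX genes, MEIS3 (-0.48 ± 0.11), HOXB9 (-0.40 ± 0.11) and HOXA10 (-0.32 ± 0.09) fell and HOXD10 (0.53 ± 0.16) rose (6 and 1 adjusted over the list alone). For the HOX list, camera gave a Benjamini-Hochberg adjusted p = 0.0119 (adjusted p = 0.297 with an estimated correlation). The list means of pinometostat replicates 2 and 4 (3.603 and 3.595 log2 CPM) lay within the DMSO range of 3.548 to 3.673, and those of replicates 1 and 3 (3.527 and 3.389) below it. Of 41 chromatin remodeller genes, SMARCD2 (-0.49 ± 0.09) fell and YEATS4 (0.52 ± 0.15) rose (1 and 0 adjusted over the list alone). For the chromatin remodeller list, camera gave a Benjamini-Hochberg adjusted p = 0.0157 (adjusted p = 0.297 with an estimated correlation). Of 33 immediate-early genes, NR4A1 (-0.62 ± 0.16) fell, also adjusted over the list alone, with a camera Benjamini-Hochberg adjusted p = 0.0375 (adjusted p = 0.297 with an estimated correlation), and without H2A with DMSO replicate 1 (0.0601) or replicate 2 (0.0546) the list was not called, nor with the GC trend removed (0.203), nor with fry (adjusted p = 0.0726). The list mean of pinometostat replicate 2 (3.121 log2 CPM) lay within the DMSO range of 3.082 to 3.298. The 33 replication-dependent histone genes had a median of 0.30 and the 13 kidney developmental markers of -0.28, with 0 members of either passing, alone or adjusted over the list alone. Their camera Benjamini-Hochberg adjusted p values were 0.0173 and 0.0137 (adjusted p = 0.297 with an estimated correlation for both), and fry did not call the histone list (adjusted p = 0.0554). Of 32 hypoxia and glycolysis genes, the glycolytic genes PFKP (-0.55 ± 0.12), GPI (-0.50 ± 0.09), ALDOA (-0.47 ± 0.13) and ENO1 (-0.38 ± 0.11) fell, with the same count adjusted over the list alone and a camera Benjamini-Hochberg adjusted p = 0.0463 (adjusted p = 0.699 with an estimated correlation). Without H2A with DMSO replicate 3 (0.179) or pinometostat replicate 1 (0.514) that list was not called. Its mean was 6.270 log2 CPM in pinometostat replicate 1 and 6.599 to 6.710 in the other pinometostat libraries, within the DMSO range of 6.501 to 6.775.

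**Figure D3:**
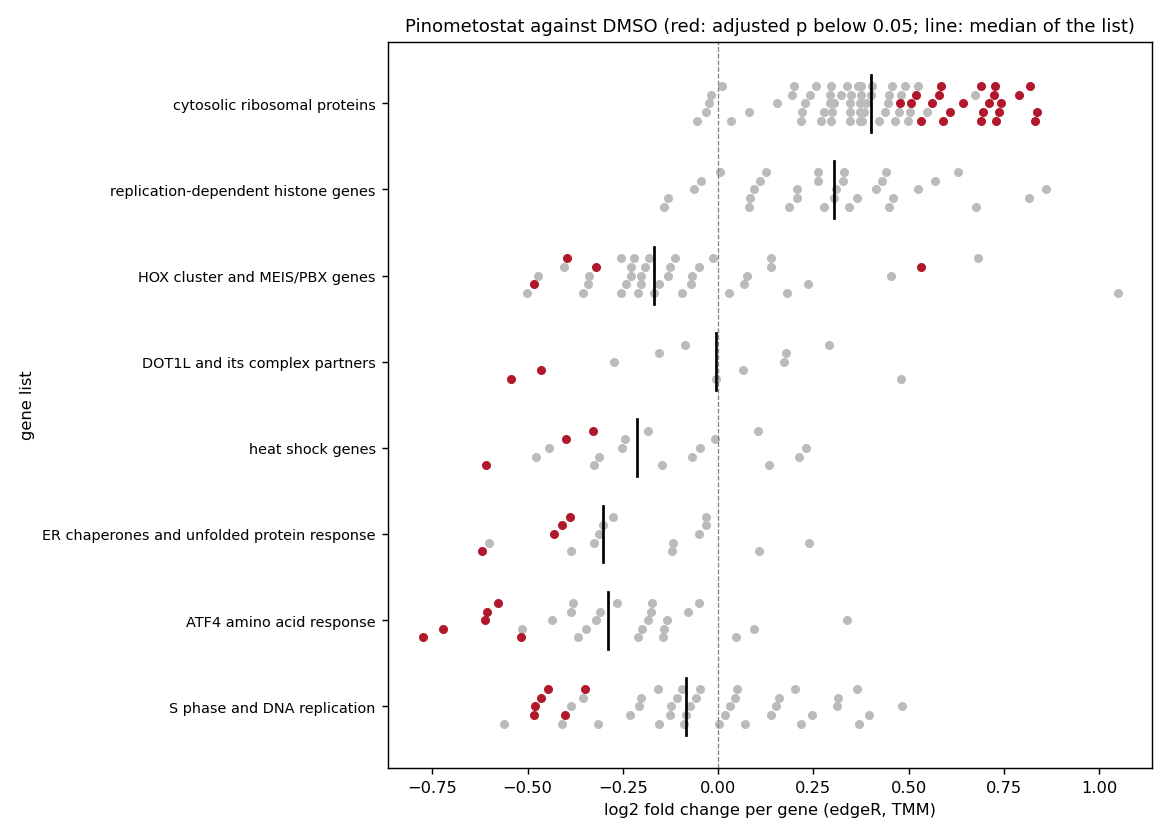
Log2 fold change of pinometostat against DMSO (n = 4 per group, TMM scaling) for the tested members of each gene list, with points for genes, red for an adjusted p below 0.05 and a line for the median. Of 77 ribosomal protein genes 23 rose, with a median of 0.40, and the ATF4, ER chaperone and heat shock lists held 6, 4 and 3 genes that fell and 0 that rose. The sign of the median changed with the scaling for DOT1L partners, G2/M genes and p53 targets.

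The other 13 lists were not called with pinometostat, among them the blood cell markers, which had too few tested members for a list test. Of 61 MYC target and ribosome biogenesis genes, NCL (-0.51 ± 0.14), MCM5 (-0.45 ± 0.10), FARSA (-0.42 ± 0.09) and PES1 (-0.34 ± 0.10) fell. Of 43 S phase genes, 6 fell, including the helicase genes MCM7 (-0.46 ± 0.11) and MCM3 (-0.35 ± 0.08) and the thymidine kinase TK1 (-0.40 ± 0.09), and 0 rose (11 fell and 4 rose adjusted over the list alone). Of 41 G2/M genes, TPX2 (-0.44 ± 0.10) and KIF2C (-0.42 ± 0.10) fell. Of 11 genes for DOT1L and its partners, MEN1 (-0.54 ± 0.11) and MLLT1 (-0.47 ± 0.13) fell. Of 18 mesenchymal markers, COL5A1 (-0.62 ± 0.11), COL6A1 (-0.58 ± 0.10) and ACTA2 (-0.57 ± 0.13) fell (3 fell and 2 rose adjusted over the list alone). Of 24 cholesterol genes, DHCR7 (-0.38 ± 0.11) fell and HSD17B7 (0.52 ± 0.16) rose (2 and 1 adjusted over the list alone). Of 24 p53 targets, BAX (-0.44 ± 0.12) fell and FAS (0.69 ± 0.19) rose (2 and 1 adjusted over the list alone). IFI44L (1.02 ± 0.23) rose among 23 interferon-stimulated genes, and H2AFY2 fell among 11 variant histone genes (2 fell adjusted over the list alone). Of 8 BET-inhibitor-induced markers, 13 mitochondrial mRNAs, 14 neuronal and 3 blood cell markers, 0 passed. The counts adjusted over the list alone were the same for the lists without a second count. Leaving out a single library brought a call for the MYC targets (H2A with DMSO replicate 1 or 2, pinometostat replicate 1 or 3, JQ1 replicate 1 or E92K replicate 4, camera adjusted p from 0.0181 to 0.0476). It did so for the S phase genes (the same libraries, and E92K replicate 1 or JQ1 replicate 4, adjusted p from 0.0194 to 0.0453), the mesenchymal markers (H2A with DMSO replicate 4 or pinometostat replicate 1 or 3, 0.0248 to 0.0313) and the mitochondrial mRNAs (JQ1 replicate 1, 0.0101). With the GC trend removed, the S phase (camera adjusted p = 0.0156) and G2/M genes (0.0109) were called. With library size alone the MYC targets (0.0360) and mesenchymal markers (0.0488) were, and the latter with the replicate block (0.0274).

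The number of genes called with pinometostat changed with the libraries and tools used. It was 283, 782 and 676 without H2A with DMSO replicate 1, 2 and 3, and 447, 708, 690 and 718 without pinometostat replicate 1, 2, 3 and 4. It was 3701 without JQ1 replicate 1, and 4610 with the 8 libraries of both groups alone, which leaves out JQ1 replicate 1 and E92K replicate 4. DESeq2 called 2348, limma-voom 1613 and limma on log2(TPM + 1) 457. Removal of the GC trend left 942 calls, of which 681 were shared. In 26.3% of tested genes the groups did not overlap, where chance gives 2.86%. Of the changed genes 44.1% were higher, against 32.6% with library size alone, 57.2% with the upper quartile, 15.1% on TPM, 27.6% with the GC trend removed and 52.3% with library quality weights. It was 27.9% without H2A with DMSO replicate 1 and 29.2% without E92K replicate 4.

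The comparison of E92K with H2A asked whether transcript levels differ between cells with the vector for the acidic patch mutant and cells with that for wild-type H2A, both with DMSO. H2A genes of the cells were still counted, such as HIST3H2A at 50.9 ± 9.71 CPM in E92K. The mutant's share of all H2A protein was not measured in these data. The mutation cannot be told apart from another difference between the H2A and E92K cells. Of 17306 genes, 0 changed (edgeR quasi-likelihood, smallest Benjamini-Hochberg adjusted p = 0.266), while 1296 had an unadjusted p below 0.05. DESeq2 called 4 genes and limma-voom 0. HEXIM1 (0.21 ± 0.17, edgeR Benjamini-Hochberg adjusted p = 0.723), MYC (-0.52 ± 0.38, adjusted p = 0.703), HOXA9 (0.05 ± 0.11, adjusted p = 0.897), MEIS1 (0.21 ± 0.11, adjusted p = 0.656), DOT1L (-0.33 ± 0.15, adjusted p = 0.656) and BRD2 (-0.04 ± 0.11, adjusted p = 0.917) did not pass. The share of genes whose groups did not overlap was 5.17%, where chance gives 2.86%.

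The H2A genes HIST2H2AA4 (ENSG00000272196, chromosome 1, 149851061 to 149851624) and HIST2H2AA3 (ENSG00000203812, chromosome 1, 149842188 to 149842736) had log2 fold changes of -1.37 ± 0.25 and -1.39 ± 0.27 in the E92K cells, with edgeR Benjamini-Hochberg adjusted p of 0.266 and 0.438 over all genes. They were singled out after their values were seen, and are near-identical copies whose reads cannot be assigned with certainty. Adjusted over the list alone both fell among 33 replication-dependent histone genes. The genes called in other settings were also chosen after their values were seen. DESeq2 called HIST2H2AA3 (-1.40), HIST2H2AA4 (-1.37), SLIT3 (-0.63) and RANBP6 (0.35). With no filter on low counts the 4 genes were HIST2H2AA4 (-1.38), MGP (-2.27), MIR17HG (1.02) and PCDH19 (-1.05). Without JQ1 replicate 1 the 4 were HIST2H2AA4 (-1.38), MIR17HG (1.01), PCDH19 (-1.06) and SLIT3 (-0.65), and without H2A with DMSO replicate 1 MGP alone (-2.65). Without both JQ1 replicate 1 and E92K replicate 4 the 3 genes were HIST2H2AA4 (-1.31), MIR17HG (1.02) and PCDH19 (-0.89), and with the mitochondrial share as a covariate the 4 were HIST2H2AA4 (-1.26), LGALS3BP (-0.55), PCDH19 (-0.84) and SLIT3 (-0.58).

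Of the 24 lists, 3 were called with E92K (limma camera, Benjamini-Hochberg over lists), and 0 held with an estimated correlation (adjusted p = 0.800 for all 3). Of 77 ribosomal protein genes, 63 had a positive fold change, with a median of 0.14. For the ribosomal protein list, camera gave a Benjamini-Hochberg adjusted p = 0.000572 (adjusted p = 0.800 with an estimated correlation). Of 32 hypoxia and glycolysis genes, 5 did, with a median of -0.11. For the hypoxia list, camera gave a Benjamini-Hochberg adjusted p = 0.00378 (adjusted p = 0.800 with an estimated correlation). Of 41 G2/M genes, 29 did, with a median of 0.10 (-0.04 on TPM). For the G2/M list, camera gave a Benjamini-Hochberg adjusted p = 0.0441 (adjusted p = 0.800 with an estimated correlation). The ribosomal protein genes were not called without E92K replicate 4 (0.410), the library with the high mitochondrial share, or without H2A with DMSO replicate 1 (0.436). Their means in E92K replicates 2 and 3 (10.703 and 10.425 log2 CPM) lay within the DMSO range of 10.348 to 10.731. The hypoxia genes lost the call without E92K replicate 4 (0.266), E92K replicate 3 (0.0789) or H2A with DMSO replicate 3 (0.0814), and their means in E92K replicates 1 and 2 (6.554 and 6.710 log2 CPM) lay within the DMSO range of 6.501 to 6.775. The G2/M genes lost the call without E92K replicate 1 (0.270) or 2 (0.405), H2A with DMSO replicate 2 (0.0837), 3 (0.0740) or 4 (0.0778), or any pinometostat library (0.0501 to 0.0542), and with the GC trend removed (0.447). The G2/M mean of E92K replicate 4, 6.401 log2 CPM, lay below all 4 DMSO libraries (6.427 to 6.489) and that of replicate 3 within their range (6.440). The 13 mitochondrial mRNAs had a median of 0.42 and were not called (camera Benjamini-Hochberg adjusted p = 0.0505), but were without E92K replicate 1 or 2, H2A with DMSO replicate 1, or JQ1 replicate 1, 3 or 4 (5.98e-06 to 0.0455), with the replicate block (0.0441) and with library size alone (0.0125). Their mean was 11.974 log2 CPM in E92K replicate 4 and 10.922 to 11.238 in the other E92K libraries, against 10.819 to 11.046 with DMSO, and without E92K replicate 4 the adjusted p was 0.443. The cholesterol genes were called without E92K replicate 1 (0.0468). No member of any of the 24 lists passed over all genes. Adjusted over the list alone, those that fell were the 2 histone genes and, among 18 mesenchymal markers, ACTA2 (-0.46) and COL6A1 (-0.33).

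The effects of JQ1 and pinometostat were compared gene by gene, as the difference of their log2 fold changes in the same fit, with doses and times that differ between the compounds. JQ1 exceeded pinometostat by 2.19 ± 0.18 for HEXIM1 (edgeR Benjamini-Hochberg adjusted p = 2.66e-07), by 2.19 ± 0.18 for HIST1H2AC (2.72e-07), by 1.93 ± 0.39 for MYC (9.19e-04) and by 0.90 ± 0.15 for HSPA5 (1.84e-04). It lay below pinometostat for OTX2 (-3.18 ± 0.27), MEIS1 (-0.74 ± 0.11), HOXA9 (-0.56 ± 0.11), RPL26 (-0.77 ± 0.13) and RPS12 (-0.71 ± 0.13), each past the threshold of the edgeR test with Benjamini-Hochberg adjustment. E92K lay below pinometostat for RPS12 (-0.74 ± 0.13, edgeR Benjamini-Hochberg adjusted p = 0.0249) and RPL26 (-0.66 ± 0.13, adjusted p = 0.0409). HIST1H2AC, HSPA5, OTX2, RPL26 and RPS12 were singled out for their change against DMSO in these same libraries. That choice favours a difference here, and RPL26 and RPS12 do not stand for other ribosomal protein genes.

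All comparisons share the 4 H2A libraries with DMSO, which alone ties their fold changes together. Among genes changed by JQ1 and pinometostat, 66 were higher with both (44.8 expected of independent lists), 84 lower with both (82.7 expected) and 162 went in opposite directions (122 expected). Without JQ1 replicate 1 and E92K replicate 4 these counts were 217 (229.8 expected), 381 (350.4) and 636 (570.0). Across 17306 genes, which are not independent replicates, the Pearson correlation of fold changes between JQ1 and pinometostat was 0.153 (simulated 0.476 with no effect, 0.0455 with split controls), with a covariance of 0.0275 against a simulated 0.0284. For E92K and JQ1 it was 0.237 (simulated 0.478, split controls 0.0883), with a covariance of 0.0314 against 0.0282. For E92K and pinometostat it was 0.469 (simulated 0.487, split controls 0.229), with a covariance of 0.0442 against 0.0282, a difference of 0.0160. The simulation gave every group the same spread per gene, estimated over all libraries, JQ1 replicate 1 among them. The simulated values therefore need not equal what the shared controls alone would give. Fold changes fell with transcript GC content for E92K (Spearman rho = -0.352) and pinometostat (-0.383) and rose with it for JQ1 (0.136). Without JQ1 replicate 1 and E92K replicate 4 these were -0.531, -0.380 and 0.0766. The trend was not shared by all E92K libraries. In deviations from the mean of all 16 libraries, rho with GC was -0.369 and -0.421 in E92K replicates 1 and 2. It was 0.0249 and 0.0875 in E92K replicates 3 and 4. The pinometostat libraries ran from -0.368 to -0.179, and those of H2A with DMSO from -0.112 to 0.288. Fold changes fell with exonic gene length across genes for E92K (Spearman rho = -0.202) and pinometostat (-0.149) and hardly varied with it for JQ1 (0.0113). Without JQ1 replicate 1 the JQ1 value was 0.158. It was negative without H2A with DMSO replicate 3 (-0.0193) or 4 (-0.0258) or JQ1 replicate 2 (-0.00617), 3 (-0.02105) or 4 (-0.0454). The E92K value was -0.0855 without E92K replicate 4 and -0.133 without H2A with DMSO replicate 1. With the GC trend removed, the length values were -0.305 (E92K), -0.250 (pinometostat) and 0.0421 (JQ1).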

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

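All tests of explanations below were chosen only after the result was seen, except those of olfactory receptor genes and of shared sequence words. In 21 of 164 group values tested a library lay far from the other 3 of its group, and chance gives that in about 1 in 20 groups.

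JQ1 replicate 1 and E92K replicate 4 stood apart. In JQ1 replicate 1 the mitochondrial genome took 16.47% of counts (others 3.045 to 3.693), the top 10 genes took 15.71% (6.616 to 7.34) and the count-weighted exonic length was 4313 bases (4979 to 5106), and in E92K replicate 4 the top 10 genes took 8.528% (6.673 to 6.976). Mitochondrial counts alone are argued against as the cause by the nuclear genes, which a larger mitochondrial share would dilute alike, so that scaling would restore them. Their median absolute log2 deviation from the group after TMM scaling was 0.5141 for JQ1 replicate 1 and 0.308 for E92K replicate 4, above the highest of the other 14 libraries (0.256). A sample without JQ1 is argued against as well, since 82.53% of the 3194 genes called without JQ1 replicate 1 moved in the called direction in it (95.7% to 99.2% for the other JQ1 libraries, each on the genes called without it). A state of the RNA or library shared by both may contribute, as their deviations correlated across genes at 0.7138, where the highest other pair of a JQ1 and an E92K library gave 0.404; no biological explanation was tested.

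Library quality weights gave 749 genes for E92K on 8 libraries, but 5 of 35 splits of these libraries gave as many, so chance cannot be excluded. The highest other split gave 3945 genes, several times the real count, which points to a structure of the samples: it set H2A with DMSO replicates 1, 2 and 3 and E92K replicate 3 against the rest. With edgeR the real count for E92K was 0 and the highest other 0, so that all 35 of 35 splits had to give as many and nothing about chance follows. For JQ1 (1872 genes) and pinometostat (4610 genes), 1 of 35 splits, the real one, gave as many, and the highest other gave 0. A share of 1 of 35 is the smallest that these splits can give. It speaks only against an arbitrary grouping of these samples, which may be technical, and cannot tell the compound from another difference between the groups.

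Non-coding genes and pseudogenes were more often higher than lower with pinometostat. GC content as the whole reason is argued against, since their median fold change minus that of protein-coding genes was 0.2915 ± 0.00895 (bootstrap SD over genes, 3198 genes) before and 0.3006 ± 0.00975 after removal of the GC trend. This SD comes from resampling genes with the libraries fixed, so it leaves out the spread between samples. Genomic DNA is argued against too: the summed CPM of 836 olfactory receptor genes had a log2 ratio of -0.1196. What stays open is the trend itself. The deviations of pinometostat libraries had a mean Spearman rho with GC of -0.2722 (DMSO 0.1546, two-sided exact permutation p = 0.0286). E92K replicate 2, however, reached -0.4207. A technical GC trend and an effect of pinometostat on GC-rich genes therefore cannot be told apart. The difference was also seen in the E92K cells, given no inhibitor, against the same DMSO libraries, with medians of 0.114 for long non-coding genes, 0.0991 for pseudogenes and -0.0150 for protein-coding genes (0.281, 0.255 and -0.0177 with pinometostat). Without JQ1 replicate 1 and E92K replicate 4 it was smaller in the E92K cells, with medians of 0.061, 0.067 and -0.0005 (0.272, 0.247 and -0.0265 with pinometostat). The trend of fold changes with exonic length and the inhibition of DOT1L stay open and were not tested.

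HIST2H2AA3 and HIST2H2AA4 had lower values in the E92K cells, short of the threshold of the edgeR test. Of the 50-base words of HIST2H2AA4, 97.09% are in HIST2H2AA3, so the copies share reads. Their summed CPM was 2.13 ± 0.604 in E92K and 5.55 ± 1.21 in H2A with DMSO (log2 ratio -1.383, n = 4), which tests nothing further, since both copies were singled out for being lower. The other 31 replication-dependent histone genes had a median of -0.04982. Reads of the lentiviral wild-type H2A counted on these genes and a lower level of the endogenous transcripts cannot be told apart without the vector sequence, which was not used here. An effect of the mutant on these genes is a hypothesis that these values leave open.

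The following values were far from the other 3 libraries of the group and are given without an explanation. Pinometostat replicate 3 had a count-weighted exonic length of 4725 bases (others 4875 to 4903), a mean log2 CPM of BET and elongation genes of 5.455 (5.55 to 5.56), of mitochondrial mRNAs of 11.41 (11.18 to 11.2) and a BRD3 level of 48.01 CPM (54.06 to 54.87). Pinometostat replicate 1 had a mean of heat shock genes of 7.006 log2 CPM (7.394 to 7.4). JQ1 replicate 1 had means of 8.069 log2 CPM for variant histones (7.746 to 7.798), 6.214 for DOT1L partners (6.457 to 6.5), 6.374 for S phase genes (6.557 to 6.589) and 13.42 for mitochondrial mRNAs (10.69 to 10.98). Its CPM was 213.1 for HEXIM1 (111.2 to 121.2) and 178.4 for MYC (796.6 to 841.2). E92K replicate 3 had a mean of replication-dependent histones of 0.372 log2 CPM (0.5521 to 0.5664). E92K replicate 4 had a mean of neuronal markers of 2.793 log2 CPM (3.016 to 3.061), 37.71 CPM of HOXA9 (44.71 to 45.42) and 21.07 CPM of MEIS1 (16.39 to 16.82). H2A with DMSO replicate 1 had a mean of neuronal markers of 3.239 log2 CPM (2.999 to 3.035), and replicate 3 had 13.87 CPM of MEIS1 (15.63 to 15.96).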

How the results depend on the processing

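Chosen after seeing the data were the fits with quality weights, the mitochondrial covariate, the GC offset, without JQ1 replicate 1 and E92K replicate 4, and without libraries outside a comparison. The medians of 11 (E92K), 11 (JQ1) and 3 (pinometostat) lists changed sign under another scaling, which also moved the median of all genes. Against edgeR's 0 for E92K (1296 genes at an unadjusted p below 0.05; limma-voom 0), DESeq2, no filter and the mitochondrial covariate each gave 4, both libraries out 3, and quality weights 1098 (749 on 8 libraries), with 0 to 4 on leaving out single libraries. JQ1 (3044) gave 1872 on its 8 libraries, 1560 at a threshold of 0.01, and 5762 and 5555 with quality weights (16 and 8 libraries), with 2216 to 3207 on leaving out single libraries. Pinometostat (1419) gave 2348 with DESeq2, 4610 on its 8 libraries, 182 at a threshold of 0.01, 457 on TPM, 4782 with both libraries out, 5548 and 5412 with quality weights, 4794 with the covariate and 942 after the GC offset, with 283 to 3701 on leaving out single libraries. Fewer genes pass a threshold of 0.01 by construction; for the others the cause was not tested. The share of higher calls was 40.7% for JQ1 (14.25% with library size, 27.4% upper quartile, 27.0% on 8 libraries, 8.77% TPM, 48.0% GC offset, 50.7% quality weights) and 44.1% for pinometostat (32.6%, 57.2%, 45.3%, 15.1%, 27.6%, 52.3%). Lists called fell from 3, 10 and 11 (E92K, JQ1, pinometostat) to 0, 4 and 0 with an estimated correlation, and fry called 0, 11 and 8; leaving out single libraries gave 1 to 4, 10 to 13 and 10 to 14. Fold change correlations with split controls, at least 5 CPM and both libraries out were 0.0883, 0.151 and 0.0668 (E92K, JQ1), 0.229, 0.526 and 0.456 (E92K, pinometostat), and 0.0455, 0.0219 and 0.122 (JQ1, pinometostat). Length trends ran from -0.252 to -0.0855 (E92K; -0.0863 with both out), -0.0454 to 0.158 (JQ1; 0.158) and -0.185 to -0.1004 (pinometostat) on leaving out single libraries. Of 561, 1287 and 1353 values of named genes under other settings, 559, 1267 and 1183 kept direction and side of the threshold, and of 506 list values each, 473, 477 and 461 did. At this depth a 1.5-fold change was mostly missed in simulation.

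The replicate numbers do not pair the samples: 2 of 24 same-number pairs had a correlation of deviations above 0.1 (-0.557 to 0.238), and 3 of 16 libraries correlated best with their own number. With the replicate block the counts were 0 (E92K), 2363 (JQ1) and 534 (pinometostat), and with the replicate block on 8 libraries 1282 (JQ1) and 4007 (pinometostat). With the block 4, 12 and 12 lists were called.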

Other observations

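All 3 gene sets in this part were chosen, and their tests with them, after the genes of each comparison had been seen. The host genes of small nucleolar RNAs, whose spliced transcripts mostly end in decay while their introns supply the guides of ribosomal RNA modification, were singled out as higher with pinometostat. Of 21 such genes, the SNHG family with GAS5, 10 rose, 0 fell (edgeR Benjamini-Hochberg) and 20 had a positive fold change, with a median of 0.558.

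With JQ1, genes for transcription factors of development beyond the HOX clusters were singled out as lower. The set was taken by the opening letters of gene symbols, which also admit genes that are not such factors. Of its 137 genes, 63 fell and 6 rose, with a median of -0.346. Protein-coding genes with a single exon went both ways: of 351, 96 fell and 49 rose, a share of falls of 0.2735.

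The hypothesis that the host genes share a rise beyond genes of like expression and GC content was tested against 10000 random lists matched on both, of which 100% had a lower median (5th to 95th percentile -0.139 to 0.115). The lists were not matched on gene type, and long non-coding genes as a class had a median of 0.281, above that range. The test therefore cannot tell the host genes from long non-coding genes at large. Since the set was also picked for being higher in these libraries, the result describes them and supports nothing beyond.

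The hypothesis that developmental transcription factor genes share a fall with JQ1 was tested against 10000 random lists matched on expression, of which 0% had a lower median (5th to 95th percentile -0.0614 to 0.0726). For single-exon genes, 100% of matched random lists had a lower share of falls (5th to 95th percentile 0.0855 to 0.137). Both sets were picked for being lower in these libraries, so neither test supports its hypothesis, which other data would have to test.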
